A study of Mus musculus with 8 samples.

How the data were processed

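Poly(A) RNA sequencing had been carried out on kidney cortex of mice, with 4 libraries labelled Sav1 wild-type and treated with vehicle and 4 labelled Sav1-null and treated with tamoxifen. Per the labels' protocols, RNA was isolated with a silica column kit and stranded mRNA libraries were prepared. The deposited table held 1 normalized expression value per gene and library for 21705 gene names. These deposited values are a signal, not counts. Per the submitters' processing notes, Picard 1.64, SAMtools and RSEM were used with the mouse genome build mm9. The aligner, the gene annotation and whether counting used strand are not given in the sources used here. RSEM divides reads that match several genes among them by a statistical estimate, so values of near-identical copies (haemoglobin, histone, MHC class II, cytochrome P450 and solute carrier paralogs) are uncertain, and so are values of genes with an antisense partner.

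The scaling of the deposited values was read from the values themselves. In each library the upper quartile (percentile 75) of the values above 0 was 1000 after rounding, 999 in wild-type replicate 2. Low values fell on steps, and the size of a step was taken as the value of 1 read. From 92.7% to 93.3% of the values below 400 in a library lay within 0.02 read of a whole multiple of that step. This share was too low to treat the values as whole reads, so no count model was used. Dividing the total of each library by its step gave about 20500000 to 25000000 reads in the wild-type libraries and 15700000 to 20900000 in the Sav1-null libraries. From 6113 to 6485 genes were at 0 in a wild-type library and 5605 to 5963 in a Sav1-null library. A value of 3 reads corresponded to between 2.34 and 3.09 in the deposited unit. Intervals and lower bounds given below cover counting error only. The reference annotation used here belongs to another build than mm9, so no coordinates are given, and it served only for gene lengths, GC content and a comparison of symbols, of which 98.9% of the tested ones matched.

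Groups came from the sample titles. The labels do not state that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may in part be technical. No pair of libraries within a group agreed within sampling noise (chi-square per degree of freedom from 12.9 to 114 over genes with at least 20 reads in the pair), and each library was counted as 1 replicate. Genotype and treatment changed together, and the sequencing run was not stated. The sample-sheet numbers in the labels occurred once in each group, so the libraries of the groups had been numbered separately, and a run cannot be told apart from the group.

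Genes with a mean of at least 10 over the 8 libraries were tested, which left 13677 and removed 8028. One gene name, Rex2, occurred 2 times. Values were transformed to log2(value + 1) and the groups were compared in R 4.3.3 with limma 3.58.1 (linear model, moderated variances with an intensity trend, 6 residual degrees of freedom). P-values were adjusted over all tested genes by Benjamini-Hochberg and genes with an adjusted p under 0.05 were called. Log2 fold changes are Sav1-null over wild-type on the log2(value + 1) scale, which understates changes of low genes, and fold changes in the text are their antilogs. Group values are means ± SD of the deposited values (n = 4). For a group with no read, the fold is given as a lower bound against 3 reads in each of its libraries. For a group with 1 to 3 reads, the ratio of reads is given with its exact 95% interval. For Sav1 a two-sided exact permutation test over the 70 assignments was added.

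Gene lists, 41 in all, were fixed before the data were examined, from textbook knowledge of the kidney, of the Hippo and STAT3 pathways and of the other cell types and handling effects that a piece of cortex can carry. They were tested with limma camera at a preset correlation of 0.01 between genes, adjusted over the 39 lists with at least 3 tested members. The correlation was also estimated per list. In that setting camera takes its p-values on the 6 residual degrees of freedom, and at the preset correlation on a number near that of the tested genes. In addition, fry was run for directional and mixed change. Some genes stand in several lists. The genes named in the text were set by a rule fixed at the same time: Sav1, Stat3, the 10 called genes with the highest and the 10 with the lowest log2 fold change among those whose groups did not overlap and whose higher group had a mean of at least 50, and for each list up to 4 called members with the smallest p in its direction and up to 2 against it. Havcr1, Col1a1, Col3a1, Acta2, Umod, Slc12a1, Esr1, Pgr, Yap1, Ctgf, Cyr61, Socs3, Kap and Hist2h2be, and members below the filter, were chosen after their values were seen. One gene that this rule selects is not reported here.

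Alternatives fixed before the data were examined were pseudocounts of 0.5 and 10, no filter and a filter of 50, median-of-ratios rescaling, quantile normalization, limma without the trend, with array weights or with robust variances, a replicate block, and leaving out each library in turn. Added after the data were seen were equal library totals, an upper quartile taken over genes above 0 in all 8 libraries, leaving out the 24 genes of the 3 sex-related lists, and leaving out the 2 wild-type libraries with the highest Havcr1. On simulated data with 200 changed genes among 13677, in 5 simulations, the comparison of Sav1-null and wild-type libraries recovered 43.9% of genes changed 1.5-fold, 69.9% of genes changed 2-fold and 95.5% of genes changed 4-fold, with 3.61% false calls, and the changed set of 20 genes was called in 5 of 5 simulations. The simulated genes were drawn independently and most did not change, whereas 69.1% of the tested genes were called in the real data. These rates therefore need not hold for the real comparison or its lists.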

Results

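RNA of kidney cortex was sequenced from mice labelled Sav1 wild-type that received vehicle (4 libraries) and from mice labelled Sav1-null that received tamoxifen (4 libraries). Sav1 encodes salvador, the scaffold protein that couples the MST and LATS kinases of the Hippo pathway, which restrains the transcriptional co-activators YAP and TAZ. The comparison asked which transcripts of the cortex differ when Sav1 is lost, and the series title also names Stat3. Values are deposited normalized expression levels, in which the upper quartile of the values above 0 in each library lies at 1000 or, in wild-type replicate 2, at 999. Each wild-type library held about 20500000 to 25000000 reads and each Sav1-null library 15700000 to 20900000.

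Sav1 itself was lower in the Sav1-null group. The labels do not state which exons the deletion removes, so the value of the whole gene does not measure how much intact transcript remained. The wild-type libraries had values of 1504, 1743, 959 and 1193 (1350 ± 345, SD, n = 4) and the Sav1-null libraries 983, 914, 982 and 714 (898 ± 127), 66.5% of the wild-type mean. The log2 fold change was -0.56 ± 0.19 (SE), with an adjusted p of 0.0220 by limma. Wild-type replicate 3 lay inside the range of the Sav1-null group, and a two-sided exact permutation test gave p = 0.0857, where 0.0286 is the smallest p that 4 libraries against 4 allow. The call was lost without wild-type replicate 1 (log2 fold change -0.50, limma adjusted p = 0.0611), without wild-type replicate 2 (-0.43, limma adjusted p = 0.0570) and with equal library totals (-0.18, limma adjusted p = 0.376). Stat3, a transcription factor downstream of interleukin 6 family cytokines, rose from 1950 ± 193 to 5379 ± 226, a 2.76-fold increase (limma adjusted p = 1.31e-06).

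The groups also differed in sex-chromosome transcripts. Xist, the non-coding RNA that silences an X chromosome in female cells, was at 12229 ± 2922 in the Sav1-null libraries and had 1 read in all wild-type libraries together. The Y-linked genes Eif2s3y (1205 ± 88.6), Ddx3y (784 ± 58.1), Uty (548 ± 71.6) and Kdm5d (378 ± 41.3) were present in every wild-type library and had no read in any Sav1-null library, which puts them at least 455-fold, 296-fold, 207-fold and 143-fold lower. The Xist ratio was 53302 (95% interval from 9566 to 2105370). All 5 tested sex-chromosome transcripts were called, 1 higher and 4 lower, and likewise adjusted over the list alone (camera adjusted p = 0.00172, adjusted p = 0.35 with an estimated correlation). The median of this list was -9.09, or -7.69 with members of 3 or fewer reads at their bound. Genotype, treatment and sex-chromosome transcripts therefore separated the same 4 libraries from the same 4, and no difference given below can be assigned to one of them.

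**Figure D1:**
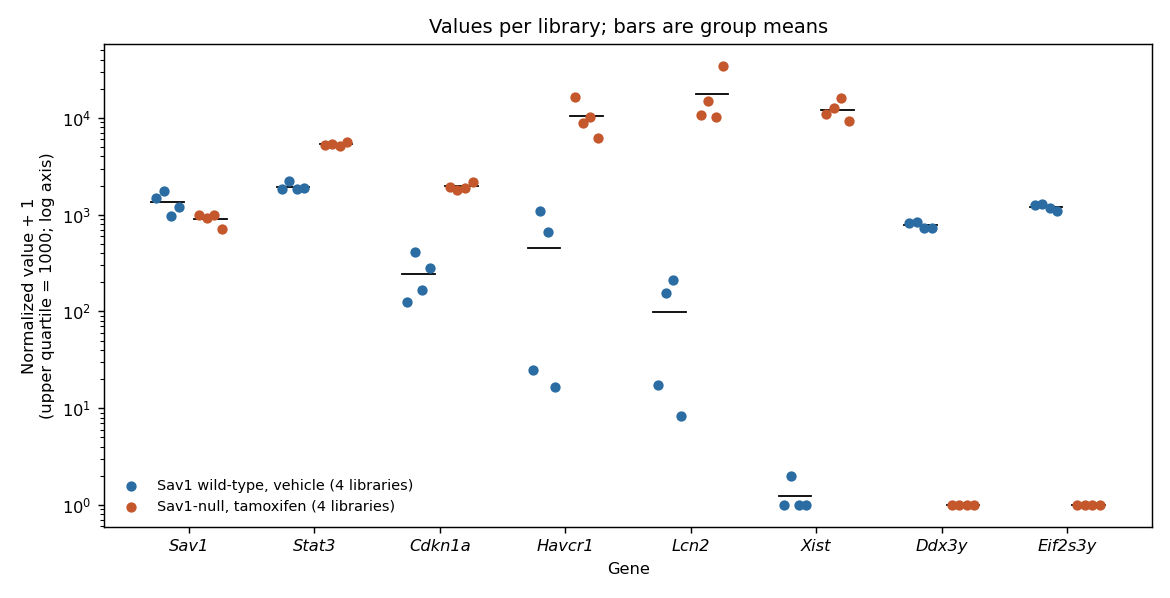
Normalized value plus 1 (log axis) of 8 genes in each of the 4 wild-type vehicle and 4 Sav1-null tamoxifen libraries, with points for libraries and bars for group means. Sav1 overlapped between the groups, Stat3 and Cdkn1a did not, Havcr1 and Lcn2 spread widely among the wild-type libraries, and Xist, Ddx3y and Eif2s3y separated the groups.

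The cortex transcriptomes differed widely. Of 13677 genes tested, 6002 were higher and 3452 lower in the Sav1-null group, and 3166 of the former and 1300 of the latter differed at least 2-fold. The first principal component separated the groups and held 84.8% of the variance. The split between directions depended on the scaling: 63.5% of calls were higher with the deposited values, 49.9% after median-of-ratios rescaling, 48.3% after quantile normalization and 81.7% with equal library totals. The median log2 fold change of all tested genes was 0.23 as deposited and moved by -0.22, -0.26 and 0.38 under these scalings.

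The 10 largest falls included 3 Y-linked genes and 3 genes of the proximal tubule or male-biased kidney lists (Slco1a1, Acsm3 and Slc7a13). Slco1a1, an organic anion transporter higher in male kidney, fell from 17769 ± 2042 to 2.60 ± 2.54 (log2 fold change -12.61). Pzp, a protease inhibitor of the alpha-2-macroglobulin family, fell by 11.82 on the log2 scale. Acsm3, a medium-chain acyl-CoA synthetase, had a log2 fold change of -11.43 (-10.66 without Sav1-null replicate 4) and the amino acid transporter Slc7a13 one of -11.35. Kap, the androgen-regulated kidney protein gene with the highest value in each wild-type library, fell 170-fold, from 856120 ± 74464 to 10068 ± 11315 (292-fold without Sav1-null replicate 3, 103-fold without replicate 4). Mpped1 had no read in the Sav1-null libraries and was at least 204-fold lower. Synpr had 1 read there (ratio 2599, 95% interval from 466 to 102709), as had Gm6300 (ratio 3687, 95% interval from 661 to 145684). The largest rises after Xist were in Mmp7, a matrix metalloproteinase of injured epithelium (1.17 ± 1.82 to 884 ± 530, log2 fold change 8.82), Il1f6, an interleukin 1 family cytokine (8.42, and 9.04 without wild-type replicate 2), and Lcn2, the secreted kidney injury marker lipocalin 2 (97.5 ± 102 to 17576 ± 11497, log2 fold change 8.37). For Lcn2 the log2 fold change was 9.09 without wild-type replicate 3 and 7.53 without wild-type replicate 4. Muc4, a membrane mucin, rose by 7.30 (6.63 without Sav1-null replicate 4) and the chemokine gene Ccl20 by 7.20. Psca, Cxcl5, Oit1 and Arhgap36 had 2 reads in the wild-type libraries together. Their ratios were 1064 (294 to 8790), 709 (196 to 5863), 683 (189 to 5642) and 567 (157 to 4687), with 95% intervals. Without Sav1-null replicate 4 the Sav1-null means of Psca, Cxcl5 and Oit1 were 323, 154 and 147 in place of 534, 353 and 340. The genes given values in this paragraph had a limma adjusted p between 2.59e-08 and 7.89e-05.

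**Figure D2:**
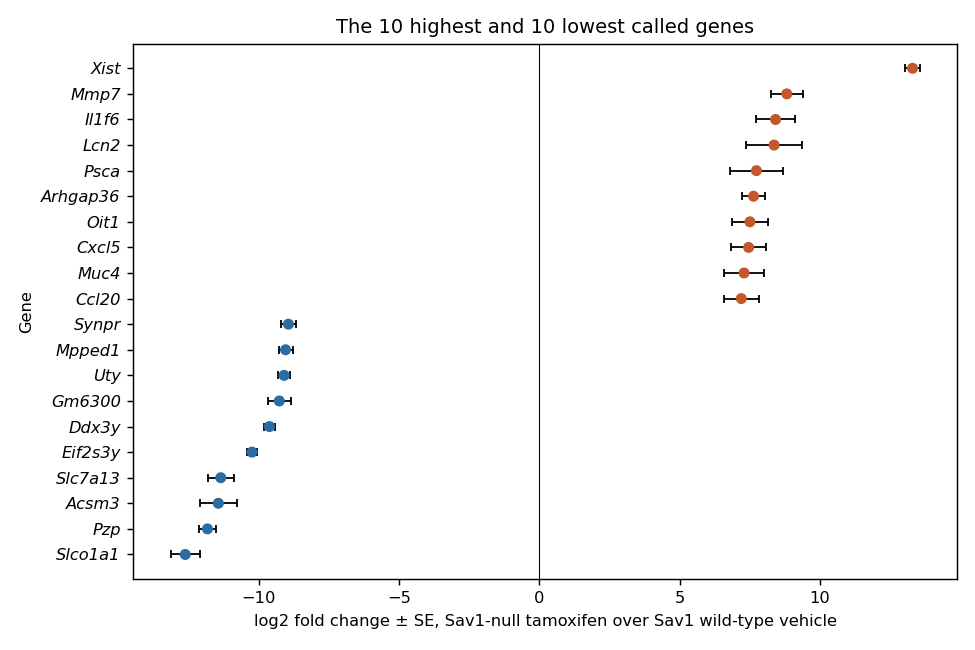
Log2 fold change (Sav1-null over wild-type, 4 libraries each) of the 10 highest and 10 lowest called genes, with bars of 1 standard error. Values run from -12.61 for Slco1a1 to 13.30 for Xist, and 3 of the lowest are Y-linked (Eif2s3y, Ddx3y and Uty).

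Markers of the proximal tubule, the segment that reabsorbs most of the filtrate, fell together. Of 40 tested, 36 fell and 0 rose (35 and 1 without Sav1-null replicate 4), with the same counts adjusted over the list alone, and the median log2 fold change was -2.17 (camera adjusted p = 2.72e-12, adjusted p = 0.35 with an estimated correlation). Slc22a12, the urate transporter URAT1, fell 8.65-fold (55576 ± 3873 to 6618 ± 1876) and Ggt1, the brush border gamma-glutamyltransferase, 4.76-fold (limma adjusted p = 2.07e-06 and 4.65e-06). The list shares members with the male-biased kidney genes, of which 10 of 11 fell (10 adjusted over the list alone, median -5.05, camera adjusted p = 5.66e-07, adjusted p = 0.35 with an estimated correlation), among them the cytochrome P450 gene Cyp2j13 (57.2-fold). Of the 7 female-biased genes 4 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.543). Abcc3, an organic anion export pump, rose 65.2-fold and the amino acid transporter gene Slc7a12 35.2-fold, while Cyp2a4 fell 17.4-fold. Slc7a12 was uneven among the Sav1-null libraries, at 971, 192, 870 and 43.3, and 66.0-fold higher without Sav1-null replicate 4.

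Genes of mitochondrial energy metabolism were lower. In the respiratory chain and TCA cycle list 33 of 34 fell and 0 rose, also when adjusted over the list alone, with a median log2 fold change of -1.11 (camera adjusted p = 1.93e-15, adjusted p = 0.35 with an estimated correlation). The complex I subunit genes Ndufv1 and Ndufa9 fell 2.48-fold and 2.13-fold, and Cox7a2 of complex IV fell 2.16-fold. In fatty acid oxidation and peroxisomes 23 of 32 fell and 5 rose, with the same counts adjusted over the list alone (median -0.78, camera adjusted p = 9.07e-06, adjusted p = 0.38 with an estimated correlation). Acads, a short-chain acyl-CoA dehydrogenase, fell 3.59-fold, Ehhadh, a peroxisomal bifunctional enzyme, 4.47-fold and Hadh 4.14-fold. Against the list, Cyp4a14, a fatty acid hydroxylase that is also among the female-biased genes, rose 88.1-fold (153 ± 116 to 11357 ± 2102), and Fabp1, the liver-type fatty acid binding protein gene, rose by 6.46 on the log2 scale.

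Markers of injured tubule epithelium rose. Of 29 tested, 28 rose and 0 fell, with the same counts adjusted over the list alone, at a median log2 fold change of 3.20 (camera adjusted p = 5.66e-07, adjusted p = 0.35 with an estimated correlation). Prom1, which encodes the surface protein CD133, rose 8.40-fold, the surface antigen gene Cd24a 8.73-fold and Dcdc2a, a doublecortin family gene, 16.5-fold. Havcr1, which encodes the injury marker KIM-1, rose 75.4-fold (limma adjusted p = 0.00194) and was uneven among the wild-type libraries, at 23.6, 1099, 665 and 15.5, against 16583, 8933, 10330 and 6275 in the Sav1-null libraries. Its rise was 43.2-fold, 153-fold, 130-fold and 37.8-fold without wild-type replicate 1, 2, 3 and 4 in turn.

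The other nephron segments did not move as a block. Of 15 collecting duct principal cell markers 14 rose and 0 fell, with the same counts adjusted over the list alone (median 1.73, camera adjusted p = 0.000271, adjusted p = 0.35 with an estimated correlation). They included Scnn1g, the gamma subunit of the epithelial sodium channel (3.33-fold), the hormone gene Stc1 (5.39-fold), and the transcription factor genes Elf5 (14.9-fold) and Gata3 (3.81-fold). Of 18 intercalated cell markers 10 rose and 3 fell (the same adjusted over the list alone, camera adjusted p = 0.414), with the water channel gene Aqp6 at 3.73-fold and the transcription factor gene Foxi1 at 2.56-fold. Thick ascending limb markers went both ways, 8 of 16 higher and 4 lower (7 and 2 without wild-type replicate 4, 4 and 5 after median-of-ratios rescaling, 9 and 2 with equal totals), also when adjusted over the list alone (camera adjusted p = 0.701). Sostdc1, a secreted antagonist of BMP and Wnt signals, and Cldn19, a tight junction gene, rose 2.53-fold and 3.64-fold, while Cldn10 fell 3.90-fold. Umod, the uromodulin gene, was at 49308 ± 917 in wild-type and 45895 ± 14933 in Sav1-null libraries and did not pass the test as deposited (limma adjusted p = 0.556), but was called higher after quantile normalization (log2 fold change 0.71, limma adjusted p = 0.0227). Slc12a1, the NKCC2 cotransporter gene, was at 7043 ± 378 and 6647 ± 3380 (limma adjusted p = 0.543). It was uneven among the Sav1-null libraries, at 8369, 6097, 9954 and 2166. Of 13 distal convoluted tubule markers 2 rose and 5 fell, also adjusted over the list alone (1 and 9 after median-of-ratios rescaling, 5 and 4 after quantile normalization, 4 and 3 with equal totals). Their median was -0.38, or -0.61 after median-of-ratios rescaling, and turned to 0.17 after quantile normalization and 0.00 with equal totals (camera adjusted p = 0.05002, not called). This list was called lower in 10 alternatives, with camera adjusted p from 0.0358 to 0.0498, among them without wild-type replicate 1 (0.0378), 2 (0.0480) or 3 (0.0485) and without Sav1-null replicate 2 (0.0371). Pvalb, the calcium-binding parvalbumin gene, fell 317-fold (654 ± 58.6 to 1.32 ± 1.25), Fxyd2, a sodium pump subunit gene, fell 2.0-fold, a call lost after quantile normalization (log2 fold change -0.10, limma adjusted p = 0.415), and Trpv5, an epithelial calcium channel gene, rose 7.21-fold.

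Podocyte markers went both ways, and most endothelial markers were not called as deposited. Of 16 podocyte markers 4 rose and 6 fell (5 and 3 with equal totals), also adjusted over the list alone, with a median of -0.19 that turned to 0.19 with equal totals (camera adjusted p = 0.543). Nphs1, which encodes the slit diaphragm protein nephrin, fell 5.12-fold, while Kirrel, another slit diaphragm gene, rose 3.93-fold. Of 18 endothelial markers 0 rose and 1 fell (0 and 4 after median-of-ratios rescaling, 0 and 11 after quantile normalization, 3 and 1 with equal totals), likewise adjusted over the list alone, with a median of -0.28 that turned to 0.10 with equal totals (camera adjusted p = 0.0900). This list was called lower without wild-type replicate 2 (camera adjusted p = 0.0480), without Sav1-null replicate 1 (0.0393), with the replicate block (0.0419) and after quantile normalization (0.0143). The number that fell was 2 without wild-type replicate 2 or Sav1-null replicate 3, 3 without Sav1-null replicate 1, and 2 without Sav1-null replicate 4, when 2 also rose. The 1 that fell over all libraries was Kdr, the VEGF receptor 2 gene (3.04-fold, limma adjusted p = 0.00290).

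**Figure D3:**
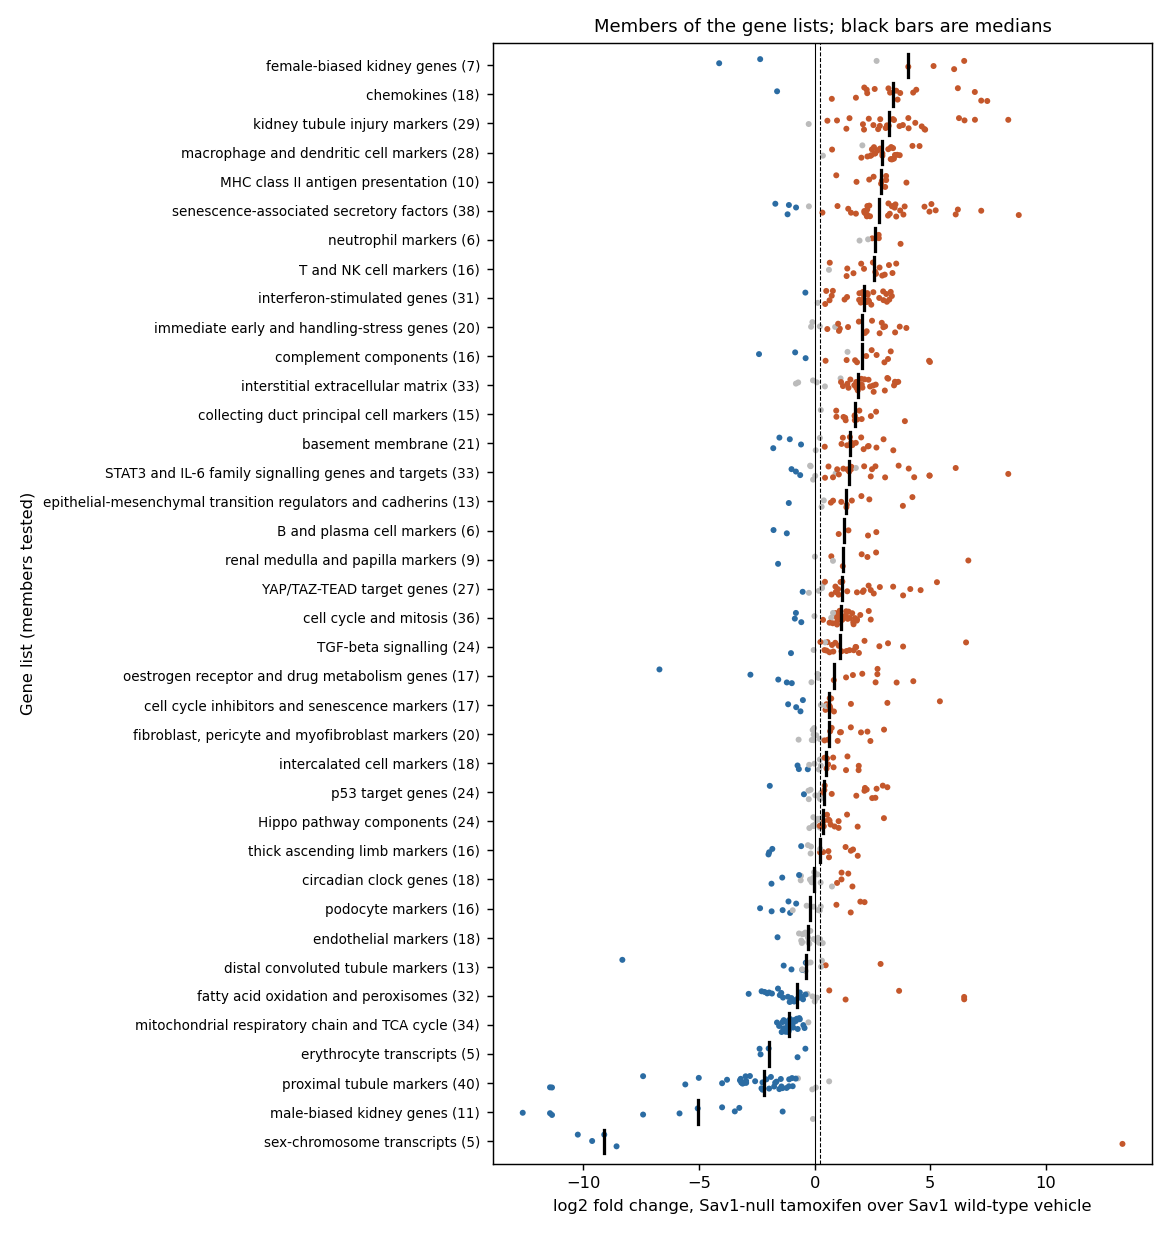
Log2 fold change (Sav1-null over wild-type, 4 libraries each) of the tested members of the gene lists with at least 5 tested members, with grey points for genes not called, black bars for list medians and a dashed line at 0.23, the median of all tested genes. Medians run from -9.09 for sex-chromosome transcripts to 4.05 for female-biased kidney genes, and those of distal convoluted tubule, podocyte, endothelial and clock genes change sign under another scaling (to 0.17 or 0.00, 0.19, 0.10 and 0.34).

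Targets of YAP and TAZ rose. Of 27 tested, 22 rose and 1 fell, with the same counts adjusted over the list alone (median 1.20, camera adjusted p = 0.000117, adjusted p = 0.35 with an estimated correlation). Edn1, which encodes the vasoconstrictor endothelin 1, rose 39.0-fold, the membrane repair gene Myof 23.9-fold, the phosphatase gene Ptpn14 5.88-fold and the receptor kinase gene Axl 5.37-fold. The matricellular genes Ctgf and Cyr61, widely used readouts of YAP, rose 2.01-fold and 1.89-fold (limma adjusted p = 0.00437 and 0.00173). Dock5 fell 1.43-fold, a call lost with equal totals (log2 fold change -0.13, limma adjusted p = 0.213). Of 24 tested Hippo pathway components 14 rose and 0 fell, also adjusted over the list alone (median 0.36, camera adjusted p = 0.0394, adjusted p = 0.35 with an estimated correlation). Tead2, a DNA-binding partner of YAP, rose 7.97-fold, Vgll4, a TEAD co-repressor gene, 3.63-fold, and Wwc1 and Taok3, which encode upstream activators of the pathway, 2.05-fold each. Yap1 rose 1.56-fold (1677 ± 103 to 2624 ± 139). The Hippo list was not called after median-of-ratios rescaling (camera adjusted p = 0.107), without wild-type replicate 4 (0.0573), without Sav1-null replicate 1 (0.0641), without Sav1-null replicate 3 (0.0528) or without the 2 wild-type libraries with the highest Havcr1 (0.0638).

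Genes of senescence changed in part. Of 17 cell cycle inhibitors and senescence markers 11 rose and 4 fell, also adjusted over the list alone (median 0.64, camera adjusted p = 0.281). Cdkn2b, which encodes the inhibitor p15, rose 42.6-fold and Cdkn1a, which encodes p21, 8.84-fold (244 ± 127 to 1957 ± 154, limma adjusted p = 2.34e-05). Lmnb1, the lamin B1 gene, usually low in senescent cells, rose 2.97-fold, and Glb1, the gene of the lysosomal enzyme behind senescence-associated beta-galactosidase, fell 2.21-fold. Cdkn2c fell 1.53-fold. Cdkn2a was below the filter, with 0 in all wild-type libraries and at most 6 reads in a Sav1-null library. Of 24 p53 targets 13 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.136). The antiproliferative gene Btg2 rose 4.52-fold, Phlda3 5.61-fold and Pmaip1, which encodes the pro-apoptotic protein NOXA, 6.39-fold, while Dcxr fell 3.83-fold. Senescence-associated secretory factors rose in 33 of 38 and fell in 4, with the same counts adjusted over the list alone (median 2.78, camera adjusted p = 0.000122, adjusted p = 0.35 with an estimated correlation). Among them were the cytokine genes Lif (31.1-fold) and Csf1 (14.8-fold) and the protease gene Mmp14 (14.3-fold), against falls of Vegfa (1.74-fold) and Il15 (2.25-fold). Il6 was below the filter, with at most 2 reads in a library. Cell cycle and mitosis genes rose in 29 of 36 and fell in 3 (14 and 3 after quantile normalization, 33 and 1 with equal totals), also adjusted over the list alone (median 1.13, camera adjusted p = 0.00271, adjusted p = 0.55 with an estimated correlation), with the spindle checkpoint gene Bub1b at 5.37-fold and the replication licensing genes Mcm3 and Mcm2 at 3.18-fold and 2.01-fold. The median of the cell cycle list was 0.43 after quantile normalization.

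In the list of STAT3 and interleukin 6 family genes and targets 24 of 33 rose and 3 fell, with the same counts adjusted over the list alone (median 1.5, camera adjusted p = 0.00287, adjusted p = 0.35 with an estimated correlation). Osmr, the oncostatin M receptor gene, rose 16.7-fold, the proto-oncogene Myc 12.4-fold, and Socs3, a feedback inhibitor induced by STAT3, 31.3-fold (31.4 ± 15.2 to 991 ± 438). Ccnd1, the cyclin D1 gene, fell 1.75-fold, a call lost after quantile normalization (log2 fold change -0.20, limma adjusted p = 0.137). Il11ra1 fell 1.54-fold, a call lost with equal totals (-0.24, limma adjusted p = 0.0786).

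Extracellular matrix genes rose. Of 33 interstitial matrix genes 27 rose and 0 fell (27 and 1 adjusted over the list alone, 26 and 1 without Sav1-null replicate 1 or 3, median 1.86, camera adjusted p = 0.000957, adjusted p = 0.55 with an estimated correlation). Sparc and Tnc, which encode matricellular proteins, rose 4.05-fold and 11.4-fold, the crosslinking enzyme gene Loxl2 9.05-fold and Thbs1, the thrombospondin 1 gene, 4.45-fold. The fibrillar collagen genes Col1a1 and Col3a1 rose 11.1-fold (90.2 ± 54.8 to 910 ± 308) and 10.8-fold (199 ± 126 to 1891 ± 877, and 6.97-fold without wild-type replicate 4). Of 21 basement membrane genes 15 rose and 4 fell, also adjusted over the list alone (median 1.52, camera adjusted p = 0.0215, adjusted p = 0.35 with an estimated correlation, and 0.149 with equal totals). The laminin gene Lamc1 rose 2.99-fold, Lamb3 6.36-fold and Col18a1 4.34-fold, while Lama3 fell 3.45-fold. TGF-beta signalling genes rose in 21 of 24 and fell in 1 (22 and 1 adjusted over the list alone, median 1.10, camera adjusted p = 0.000237, adjusted p = 0.35 with an estimated correlation). Tgfb2 rose 14.1-fold, Ltbp2 93.2-fold and the integrin gene Itgav, whose product helps to release latent TGF-beta, 3.77-fold, while Bmp7, which counteracts TGF-beta in kidney, fell 2.03-fold. Fibroblast, pericyte and myofibroblast markers rose in 12 of 20 and fell in 0 (9 and 1 after median-of-ratios rescaling, 7 and 5 after quantile normalization), also adjusted over the list alone (median 0.62, camera adjusted p = 0.144). The list was called without Sav1-null replicate 4 (camera adjusted p = 0.0177) and with array weights (0.0339). Pdpn rose 7.99-fold, Thy1 5.31-fold and S100a4 4.86-fold, whereas Acta2, the smooth muscle actin gene of myofibroblasts, was at 649 ± 54.9 and 697 ± 167 (limma adjusted p = 0.742) and was called higher without Sav1-null replicate 4 (log2 fold change 0.26, limma adjusted p = 0.0187), with array weights (0.24, limma adjusted p = 0.0487) and with equal totals (0.45, limma adjusted p = 0.0293). Of 13 epithelial-mesenchymal transition regulators and cadherins 10 rose and 1 fell, also adjusted over the list alone (median 1.37, camera adjusted p = 0.0224, adjusted p = 0.35 with an estimated correlation, and 0.112 with equal totals). The members with the smallest p were epithelial or fetal kidney genes: Cdh6, a cadherin of the developing nephron (18.7-fold), the epithelial adhesion gene Epcam (5.15-fold) and the epithelial transcription factor gene Grhl2 (4.06-fold). Ovol1 fell 2.17-fold.

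Markers of macrophages, MHC class II genes and T cell markers rose. Of 28 macrophage and dendritic cell markers 26 rose and 0 fell, with the same counts adjusted over the list alone (median 2.93, camera adjusted p = 5.66e-07, adjusted p = 0.35 with an estimated correlation). The integrin genes Itgam and Itgax rose 18.7-fold and 10.8-fold, and the complement gene C1qa 9.07-fold. All 10 MHC class II genes rose, also adjusted over the list alone (median 2.89, camera adjusted p = 0.000528, adjusted p = 0.35 with an estimated correlation), H2-Ab1 by 7.48-fold and H2-Eb1 by 8.50-fold. T and NK cell markers rose in 15 of 16 and fell in 0 (9 and 0 after quantile normalization), also adjusted over the list alone (median 2.57, camera adjusted p = 0.00207, adjusted p = 0.35 with an estimated correlation, and 0.109 with the filter at 50). Their median was 1.26 after quantile normalization. The kinase gene Lck rose 6.28-fold and Il7r, the interleukin 7 receptor gene, 10.3-fold. Of 6 tested B and plasma cell markers 4 rose and 2 fell (1 and 2 after quantile normalization, 4 and 1 with equal totals), also adjusted over the list alone (camera adjusted p = 0.701), with the transcription factor gene Spib 4.95-fold higher and Igj, the immunoglobulin J chain gene, 3.42-fold lower. The call of Igj was lost without wild-type replicate 1 (log2 fold change -1.60, limma adjusted p = 0.0569) and without the 2 wild-type libraries with the highest Havcr1 (-1.91, limma adjusted p = 0.0782), and its fall was 2.16-fold without Sav1-null replicate 4. Of these markers 0 fell without wild-type replicate 1, and 1 without wild-type replicate 2 or 4 or Sav1-null replicate 1, 2 or 4. Of 6 tested neutrophil markers 4 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.183), among them the G-CSF receptor gene Csf3r (6.84-fold). All 4 stood highest in Sav1-null replicate 4, at 2.80 to 6.05 times the next Sav1-null library, with Csf3r at 25.8, 39.1, 36.3 and 147. Without that library 2 of the markers passed the filter and 1, Csf3r, was called (4.74-fold, limma adjusted p = 0.000546).

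Chemokine, interferon-stimulated and complement genes rose. Chemokines rose in 17 of 18 and fell in 1, with the same counts adjusted over the list alone (median 3.39, camera adjusted p = 0.000237, adjusted p = 0.35 with an estimated correlation). The mucosal chemokine gene Cxcl17 rose 121-fold (1.43 ± 1.30 to 270 ± 88.2) and Ccl6 12-fold, while Cxcl12 fell 3.08-fold. Interferon-stimulated genes rose in 29 of 31 and fell in 1 (0 without wild-type replicate 1), also adjusted over the list alone (median 2.12, camera adjusted p = 8.61e-06, adjusted p = 0.38 with an estimated correlation). The immunoproteasome gene Psmb8 rose 7.78-fold, the antiviral gene Ifit3 5.10-fold and the peptide transporter gene Tap1 3.79-fold. Complement components rose in 12 of 16 and fell in 3, also adjusted over the list alone (median 2.03, camera adjusted p = 0.0286, adjusted p = 0.48 with an estimated correlation), a call lost with the filter at 50 (camera adjusted p = 0.0837) and with equal totals (0.149). Cfi, the complement factor I gene, rose 30.8-fold and C1ra 6.40-fold, whereas Cd55, which encodes a brake on complement at the cell surface, fell 5.29-fold.

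Lists for handling, drug, tissue make-up and time of day gave the following counts. Immediate early and handling-stress genes rose in 16 of 20 and fell in 0, also adjusted over the list alone (median 2.04, camera adjusted p = 0.00270, adjusted p = 0.50 with an estimated correlation), with the transcription factor gene Klf6 at 7.47-fold and the heat shock gene Hspb1 at 15.6-fold. Oestrogen receptor and drug metabolism genes went both ways, 9 of 17 higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.914). Tamoxifen binds oestrogen receptors, and Esr1, which encodes oestrogen receptor alpha, fell 6.84-fold while its target gene Pgr rose 6.21-fold. Pgr was chosen after its values were seen. It was low and uneven in the wild-type libraries, at 2.72, 20.1, 5.74 and 2.06, against 45.3, 55.7, 34.8 and 24.6 in the Sav1-null libraries. A response to the drug was not tested. Circadian clock genes rose in 5 of 18 and fell in 3 (4 and 3 adjusted over the list alone), with a median of -0.04, a mean of 0.10 and a median of 0.34 with equal totals (camera adjusted p = 0.618). The clock output genes Tef and Hlf fell 2.64-fold and 3.64-fold. Erythrocyte transcripts fell in 5 of 5, also adjusted over the list alone (median -1.99, camera adjusted p = 0.00333, adjusted p = 0.35 with an estimated correlation), the haem synthesis gene Alas2 by 5.20-fold and the alpha-globin gene Hba-a2 by 3.96-fold. Renal medulla and papilla markers rose in 6 of 9 and fell in 1 (7 and 1 adjusted over the list alone, camera adjusted p = 0.136), and this list was called higher after quantile normalization (median 1.30, camera adjusted p = 0.0188). Slc14a2, the urea transporter gene of the medulla, had 1 read in the wild-type libraries (ratio 580, 95% interval from 104 to 22951), and Akr1b3, the aldose reductase gene, fell 2.99-fold. Of 3 tested adipocyte markers 2 fell, also adjusted over the list alone (camera adjusted p = 0.192), and 1 rose without Sav1-null replicate 4. Of the 2 that fell, 1 stands in the proximal tubule list as well. Of the skeletal muscle markers 2 passed the filter and 1 fell, and of the adrenal markers 1 passed and was called higher, in both cases the same adjusted over the list alone. The muscle marker that fell was Pvalb, given above among the distal convoluted tubule markers. The adrenal gene, Star, had a log2 fold change of 0.51 that turned to -0.46 after quantile normalization. Its call was also lost after median-of-ratios rescaling (limma adjusted p = 0.207), without the filter (0.0631), without the 2 wild-type libraries with the highest Havcr1 (0.226) and in 6 of the 8 fits without 1 library (limma adjusted p from 0.0592 to 0.105), those without wild-type replicate 2, 3 or 4 or Sav1-null replicate 1, 2 or 3.

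Over the 39 lists tested by camera, 18 were called higher and 6 lower at the preset correlation, and 0 of 39 were called with the correlation estimated per list (adjusted p from 0.35 to 0.947). By fry, 35 lists moved on balance in one direction and 38 changed in either direction, a test that does not compare a list with other genes. Placing members with 3 or fewer reads in a group at their bound moved no list median but that of the sex-chromosome transcripts. In lists without counts for other scalings above, any count of members higher or lower that another scaling moved by over 1.5 times moved by at most 3 genes. Moves of a smaller ratio could reach more genes. After quantile normalization 28 proximal tubule markers fell and 1 rose, in place of 36 and 0. Under the same scaling 21 interstitial matrix genes rose and 1 fell, in place of 27 and 0. With equal totals 19 p53 targets rose, in place of 13. After median-of-ratios rescaling 10 Hippo components rose and 2 fell, in place of 14 and 0.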

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

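The genes examined here include some chosen after their values were seen, as named under the processing, and the test for outlying libraries was fixed beforehand. In each group of 4 libraries the distance of the highest or lowest library from its nearest neighbour was compared with the range of the group and set against Dixon's 95% critical value. Over the 146 tested genes named in the text this made 287 tests, of which 15 passed, and chance alone passes about 1 in 20. No biological or technical explanation was tested for single libraries.

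Wild-type replicate 2 stood apart for Stat3, at 2238 against 1832 to 1877 in the other wild-type libraries, and for Sostdc1, at 1025 against 1187 to 1212. The same library held the lone wild-type reads of Xist (0.989), Arhgap36 (1.68), Oit1 (1.68) and Slc14a2 (0.838), with 0 in the other wild-type libraries. Wild-type replicate 4 was lowest for Axl, at 201 against 263 to 276, and for Lif, at 9.28 against 15.3 to 16.3. Sav1-null replicate 4 was highest for Oit1 (919 against 131 to 172), Cxcl5 (950 against 129 to 172) and Fabp1 (338 against 97.8 to 120) and lowest for Acsm3 (1.27 against 14.4 to 21.1). Sav1-null replicate 1 was highest for Vgll4, at 411 against 377 to 382, and held the lone Sav1-null read of Synpr (0.781). Sav1-null replicate 3 held the lone Sav1-null read of Gm6300 (0.79).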

How the results depend on the processing

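The alternatives with equal library totals, with another set of genes for the upper quartile, without the sex-related genes and without 2 wild-type libraries were chosen after the data were seen, and the others before. Of the 145 genes other than Sav1, 136 kept their side of the threshold and, where called, their direction in each alternative that tested them. A gene that an alternative filtered or left out, such as those of the sex-related lists, was not compared in it. A change of sign in a gene called neither as deposited nor in the alternative was not counted, as for Slc12a1. Over all results and alternatives, 3 values of these genes reversed, 17 of them, 3 of Sav1 and 10 list values lost their call, and 3 gene values and 17 list values gained one. Counted in this way, the reversals were all after quantile normalization: Umod at a log2 fold change of 0.71 (limma adjusted p = 0.0227), Star at -0.46 and Hist2h2be at -0.17. That normalization also gave 2044 genes higher at least 2-fold, and equal totals gave 1946 genes lower, 809 of them at least 2-fold, and a log2 fold change of -0.18 for Sav1. With the correlation between genes estimated per list, 0 lists were called higher and 0 lower. The cause of these changes was not tested. That last setting also takes its p-values on the 6 residual degrees of freedom, far fewer than at the preset correlation. The lost calls therefore cannot be put down to the correlation between genes alone. A higher correlation does not account for each list that lost its call there. The list of epithelial-mesenchymal transition regulators and cadherins had an estimated correlation of 0.002, below the preset 0.01, and was no longer called (camera adjusted p = 0.35). Leaving out each library in turn gave 5471 to 6296 genes higher, 3148 to 3632 lower, 3044 to 3284 higher and 1178 to 1384 lower at least 2-fold, 17 to 19 lists higher, 6 to 8 lists lower, and a log2 fold change of Sav1 from -0.71 to -0.43. Of the genes called with the deposited scaling, 4619 higher and 3452 lower kept their call after median-of-ratios rescaling with 0 opposite, 3981 and 3084 after quantile normalization with 42 opposite, and 6002 and 1946 with equal totals with 26 opposite. The replicate numbers of the titles did not pair the libraries: deviations of same-numbered libraries correlated between -0.17 and 0.14, and in 2 of 4 cases the best correlation was with the own number. With the replicate number as a block, 5927 genes were higher and 3391 lower, 3163 and 1302 of them at least 2-fold, 18 lists were higher and 7 lower, with the endothelial list called lower (camera adjusted p = 0.0419), Star was not called (limma adjusted p = 0.0776), and Sav1 had a log2 fold change of -0.56. Without the genes of the sex-related lists 5999 genes were higher and 3435 lower, and without the 2 wild-type libraries with the highest Havcr1, which leaves fewer samples, 5339 and 2748. Depth limits the genes near the filter, where 1 read is worth between 0.781 and 1.03, and those with no read in a group, for which only lower bounds can be given. The count models listed beforehand for unnormalized counts were not run, because the values are normalized.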

Other observations

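All tests in this part were chosen after the result they bear on was seen, except the gene length and GC test of the histone genes and the other splits of the libraries. Genes were also grouped by the stem of their symbol, which gave 228 families of at least 8 tested members, and camera at the preset correlation called 8 higher and 18 lower in the Sav1-null libraries (lowest adjusted p = 0.465 with an estimated correlation). The largest family-wide falls by p were in the mitochondrial ribosome, with 37 of 45 Mrpl genes and 23 of 29 Mrps genes lower (median log2 fold changes -0.47 and -0.48, and -0.09 for both with equal totals). The peroxin genes (Pex) were lower in 13 of 15 (median -0.71), the mitochondrial import genes (Timm) in 9 of 11 (-0.63) and the coenzyme Q synthesis genes (Coq) in 8 of 9 (-0.79). Carboxylesterases (Ces) were lower in 7 of 9 (-2.67) and glucuronosyltransferases (Ugt) in 10 of 15 (-2.60).

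Among families that were higher, Serpina serine protease inhibitors rose in 9 of 11 (median 3.92), matrix metalloproteinases in 11 of 13 (2.82), clustered beta-protocadherins (Pcdhb) in 10 of 10 (2.64) and HoxB transcription factor genes in 8 of 8 (1.57). Trim genes rose in 31 of 40 (0.83). Zinc finger genes named Zfp rose in 216 of 333 with a median of 0.61, which was 0.01 after quantile normalization. The medians of the other families named here kept their sign under median-of-ratios rescaling, quantile normalization and equal totals, but not their size. With equal totals the median of Timm was -0.25 and that of Pex -0.32. After quantile normalization that of Pcdhb was 1.41 and that of Trim 0.41. Median-of-ratios rescaling moved that of Coq to -1.02. Members of the Serpina, Ces, Ugt and Pcdhb families are close copies of one another, and their reads were divided by estimate.

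The wild-type libraries were uneven in the injury genes Lcn2 and Havcr1: Lcn2 was at 16.3, 156, 211 and 7.22 and Havcr1 at 23.6, 1099, 665 and 15.5 in wild-type replicates 1 to 4. Other injury markers varied less among them, such as Cd24a (1689, 1896, 1737 and 1463) and Prom1 (832, 600, 513 and 531). On the second principal component, which held 6.82% of the variance, Sav1-null replicate 4 stood at -51.4 and the other Sav1-null libraries between 8.46 and 29.2.

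The largest changes included sex-linked and sex-biased genes. All 8 libraries carried the sex-chromosome transcripts of their own group, as they would if the animals of the groups differed in sex, and 0 carried those of the other group, which argues against a swap of some of the libraries if each group was of 1 sex, which the labels do not state. An exchange of all libraries would give the same 0 and cannot be told apart, since the labels do not state whether the value of the whole Sav1 gene shows the deletion. Sav1 was lower in the libraries labelled Sav1-null but overlapped between the groups (exact permutation p = 0.0857), although limma called it (adjusted p = 0.0220). That 22 of 27 YAP and TAZ targets were higher cannot decide this, since treatment and sex-chromosome transcripts separate the same libraries. The members of the male-biased list alone do not account for the fall of proximal tubule markers. Without them the 36 remaining markers had an upper quartile of -1.19, below the median of 0.23 for all tested genes. Their median was -1.93, and 32 were called lower. Genes that differ by sex but are not in that list may remain among the 36. An effect of sex on other genes of the cortex, tamoxifen, Sav1 and an unstated sequencing run stay open and cannot be told apart here, since each may separate the same 4 libraries from the same 4.

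Histone genes were lower while cell cycle genes were higher. Of the 13 tested genes with a Hist symbol 12 fell and 1, Hist2h2be, rose (log2 fold change 0.51, but -0.17 after quantile normalization and not called after median-of-ratios rescaling, limma adjusted p = 0.0714), with a median of -2.19. Fewer dividing cells would not go with the cell cycle list, whose lower quartile was 0.85, above the median of all genes. That rise is part of the pattern itself, however, so it is no separate test of this explanation. After quantile normalization 14 of the 36 cell cycle genes were higher, with a median of 0.43. Gene length or GC content is argued against by 10000 random sets matched on both for the 12 genes with a length. The share of sets with a median as low was 1e-04, the smallest that number of sets can give. The sets treat genes as independent, and the genes with a Hist symbol were not a list fixed beforehand. A different capture of RNA without a poly(A) tail, the form most replication-dependent histone transcripts take, stays open as a candidate explanation and cannot be told apart from a change in the cells, since 0 of Rmrp, Rpph1 and Terc passed the filter. Some histone genes also differed within the wild-type group. Hist2h2aa1 was at 232, 231, 600 and 597 in wild-type replicates 1 to 4, and Hist1h4h at 29.0, 32.7, 76.6 and 76.3. Others did not, such as Hist1h1c at 1530, 1350, 1403 and 1449. The cause of this difference was not tested.

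The list of collecting duct principal cell markers was called higher at the preset correlation (adjusted p = 0.35 with an estimated correlation, not called) while those of the thick ascending limb, distal convoluted tubule, podocytes and endothelium were not, although 8 of 16 thick ascending limb (4 after median-of-ratios rescaling) and 4 of 16 podocyte markers rose. A smaller share of proximal tubule cells alone would raise the markers of the other resident cell types alike. The highest and lowest median of 7 such lists, intercalated cells and fibroblasts included, lay 2.11 apart (1e-04 of 10000 shuffles, the smallest that number can give). The shuffles treat genes as independent, although the correlation was estimated at 0.34 in the principal cell list and 0.80 in the endothelial list. The highest list, that of principal cells, is the one whose rise defined the pattern. The lowest median, of distal convoluted tubule markers, turned from -0.38 to 0.17 after quantile normalization. A smaller share of proximal tubule cells therefore stays open. More outer medulla in the dissected tissue stays open and cannot be told apart from a change in the cortex here: thick ascending limb markers had an upper quartile of 0.80, below the lower quartile of 1.28 for principal cell markers, but 0 libraries of outer medulla show how far such tissue would raise either. More inner medulla stays open and cannot be told apart from a change in the cortex itself, since the 7 medulla markers outside the principal cell list had a median of 0.79, with 4 higher and 1 lower, and the whole medulla list was called higher after quantile normalization (camera adjusted p = 0.0188). An increase in principal cells or in their transcripts was not tested and stays open too.

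The 8 libraries can be divided into groups of 4 in 35 ways. For the genes called higher (6002) and lower (3452), and for those changed at least 2-fold (3166 and 1300), 1 of 35 splits, the real one, gave as many. That is the smallest share this number of splits can give. The highest count in any other split was 1. Every other split mixes libraries of both groups, so the group difference adds to the spread within its groups and leaves few calls. These low counts do not show how many calls chance would give among like libraries, and chance is not excluded by them. Since a split and its mirror are one, the larger of both directions was taken for each split but the real one. For gene lists called higher (18), 3 of 35 splits gave as many, with 20 in the highest other split, and for lists called lower (6), 25 of 35 splits gave as many, also with 20 in the highest other split. The other splits with as many lists higher put 3 wild-type libraries with 1 Sav1-null library, so part of the group difference stays in them. These counts are therefore no chance rate for the lists. Chance is not excluded by this test for the numbers of lists either.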
